A study of Homo sapiens with 10 samples.

How the data were processed

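Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on MCF10Ca1h cells, a human breast cancer line of the MCF10 series, after 72 h with GSK484, an inhibitor of the histone-citrullinating enzyme PADI4, or with a control compound that the labels call GSK107. There were 10 libraries, 1 for each treatment and antibody: histone H3, H3 citrullinated at arginines 2, 8 and 17, H3K27me3, H3K4me3 and rabbit IgG. Chromatin was cut enzymatically and sequenced as single reads of 75 bp, per the labels' protocols. With 1 library per group there are no replicates, so no test between treatments was possible and none was made.

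The labels of 2 libraries contradict themselves: the H3K4me3 library and the IgG library placed in the control group carry GSK484 in their title and treatment field and CON (control) in their description. They were grouped by description, and the header of the deposited matrix likewise names an H3K4me3 ratio of GSK484 over CON. No IgG values were used here.

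The authors deposited 1 matrix of log2 ratios of GSK484 over control, per the file headers, for H3, citrullinated H3, H3K27me3 and H3K4me3, each around the start sites of 39680 RefSeq transcripts. Another track holds an RNA-seq log2 ratio of GSK484 over a compound the header calls GSK106; its RNA samples are not described in the labels used here. Per the file headers, each track covers 4 kb on either side of the start site in 800 bins of 10 bp, in the layout written by deepTools computeMatrix. Genome build hg19 and the peak caller MACS2 are named in the submitters' processing notes; no peak list was analysed here. The aligner, the read filters and the tool that made the ratio tracks are not given in the sources used here. Coordinates are hg19 positions from the matrix. Gene symbols are those of the matrix; of the 23346 genes, 22145 chosen transcripts have an accession in a RefSeq gene table of a later build, which was not used for coordinates.

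For each gene and track the deposited log2 ratio was averaged over bins within 1 kb of the start site. Where a gene had several transcripts, the one with the fewest bins at exactly 0 over the 4 ChIP tracks was taken. Genes with no bin other than 0 in a track were left out of that track. A mean of 1 or more in size was counted as a large difference; since 1 read is added in each bin, this is not the same as a 2-fold difference in reads, and counts on summed reads are given beside it. The text names, by a rule fixed before the data were examined, the 10 highest and 10 lowest protein-coding genes per antibody with at least 75% of bins not 0, then PADI4, NANOG, POU5F1, SOX2, KLF4, MYC, CD44, CDKN1A, ESR1 and KRT5, then the 2 highest and 2 lowest members of each gene list that stood apart. From each group the text gives the examples with the most reads or the clearest difference. The 26 gene lists were also fixed before the data were examined. They are pluripotency factors, breast stem cell markers, basal and luminal mammary genes, mesenchymal transition and epithelial junction genes, p53 and TGF-beta targets, Wnt, Notch and Hedgehog genes, developmental transcription factors, HOX, ribosomal protein, olfactory receptor, replication-dependent histone, protocadherin cluster and keratin-associated protein genes, KRAB zinc finger genes taken by their ZNF symbols alone and so including others, peptidylarginine deiminases, histone methylation enzymes, interferon-stimulated, cell cycle, housekeeping, blood cell, neuronal and inflammatory genes, and genes of neutrophil extracellular traps. A list was set apart when its median lay outside the central 95% of 10000 random lists of the same size, which describes these libraries and is not a test of treatment. About 1.3 of 26 lists would lie outside for each antibody by chance.

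The deposited ratios of the 4 ChIP tracks change in steps of 50 bp and take few values. Each equals log2 of (reads × scale + 1) over (reads × scale + 1) for whole numbers of reads, with the larger library of each pair scaled down (control H3 by 0.825, GSK484 citrullinated H3 by 0.854, GSK484 H3K27me3 by 0.958, control H3K4me3 by 0.961). Whole-read pairs of at most 100 reads matched over 99.9% of the non-zero H3, citrullinated H3 and H3K27me3 values and 86.8% of the more deeply covered H3K4me3 values, within the rounding of the file; at most 0.0795% of shifted decoy values matched. These steps, the pseudocount of 1 read and the scale factors were read from the values and are not recorded in the header. The recovered reads were summed over 1 kb on either side of the start site and divided by 2.48, the mean number of 50 bp steps a 75 bp read touches. The choice to recover reads, the gene lists matched on reads, the classes of promoters and their ranking by reads and the comparison of chromosomes were made after seeing the data.

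Folds between 2 libraries are ratios of scaled reads with 1 added, with exact Clopper-Pearson 95% intervals of the ratio without that addition. Reads carry no molecular identifiers, so the intervals cover counting error only. Each is for a single gene and makes no allowance for the picking of the highest and lowest among all genes. The depth is modest outside H3K4me3. The median promoter held 22.6 GSK484 and 14.5 control reads for H3, 19.4 and 15.3 for citrullinated H3, 8.06 and 5.24 for H3K27me3, and 294 and 305 for H3K4me3. Because 1 read is added before the ratio is taken, the mean log2 ratio understates differences where reads are few.

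The recovery and the averages were tested on simulated reads with the real promoter profiles, in which 50 genes per antibody were changed by each of 4 known folds. Recovered read pairs were right in at least 99.9% of steps for each antibody. Among 50 H3K4me3 promoters doubled in the simulation, over 23253 genes, the median shift was 0.70 on the deposited log2 scale and 0.98 on summed reads. For the same doubling of H3K27me3 over 23250 genes, the shifts were 0.21 and 0.88. The same 4-fold increase that moved 64% of 50 simulated H3K4me3 promoters past a mean of 1 moved 6% of the 50 H3K27me3 promoters. In a second simulation all promoters shared 1 ratio and reads were dealt at random, giving the spread that counting alone produces. It was run on the mean log2 ratio only, so the counts of genes on summed reads have no counting level beside them.

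Alternatives fixed before the data were examined were a window of 0.5 kb, the whole 8 kb window, the median of bins, the first transcript listed per gene, centring on the median of all genes, a filter on bins at 0, a threshold at the log2 of 1.5 on the mean ratio, subtraction of the H3 difference and a flank of 0.5 kb. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.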

Results

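Libraries from MCF10Ca1h breast cancer cells treated for 72 h with the PADI4 inhibitor GSK484 or with a control compound were compared at the promoters of 23346 genes, of which 18764 were represented by a coding transcript. PADI4 converts histone arginines to citrulline, and the libraries addressed whether blocking it altered H3 occupancy, H3 citrullination, the repressive mark H3K27me3 or the active mark H3K4me3. Each antibody had 1 library per treatment, so the values describe these libraries and carry no measure of variation between cultures. Recovered reads within 1 kb of start sites totalled 578529 (GSK484) and 384125 (control) for H3, 512243 and 421092 for citrullinated H3, 418535 and 306246 for H3K27me3, and 12171974 and 13498737 for H3K4me3. The control H3K4me3 library is control by its description only, its title naming GSK484, and every H3K4me3 direction below rests on that description and on the header of the authors' deposited table.

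Histone H3 reads at start sites were higher in the GSK484 library at most promoters examined. The tracks hold no values beyond 4 kb of a start site, so the rest of the genome was not measured. In the control library H3 dipped over the start site, from 1.08 scaled reads per 50 bp in the outer flank to 0.84 within 1 kb, the usual depletion of nucleosomes at promoters. In the GSK484 library the corresponding values were 1.44 and 1.54, with a maximum of 1.76 reads downstream of the start site. A shallower dip remained at the start site itself, where the central 100 bp had 0.93 of the flank value with GSK484 and 0.57 in control. The median promoter had a mean log2 ratio of 0.42 in the authors' deposited table (quartiles 0.11 and 0.68, 23264 genes), and 80.8% of genes were above 0. The median was 0.18 over the 8 kb window and with the median of bins, and 0.93 on summed reads. The ratio of total scaled promoter reads was 0.87 on the log2 scale. The mean log2 ratio was 1 or more at 1208 genes and -1 or less at 27. On summed reads, which the added read of each bin does not pull toward 0, 10879 genes were at 2-fold or more and 814 at 0.5-fold or less. The median of 0.93 on summed reads is itself close to 2-fold, so the shift shared by all genes carries many of them past it. Equal ratios for all promoters with counting noise alone gave on average 85.7 and 0 genes by the mean log2 ratio in simulation. After centring on the median of all genes the split was 46 higher and 482 lower, so the H3 directions that follow are relative to the median of 0.42. The difference was present away from promoters as well and varied by chromosome: in flanks 3 to 4 kb from start sites, the log2 ratio of total H3 reads ran from 0.05 on chromosome 13 to 0.86 on chromosome 19. Within 1 kb of start sites it ran from 0.17 on chromosome 18, where it was below the flank (0.23), to 1.28 on chromosome 16.

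**Figure D1:**
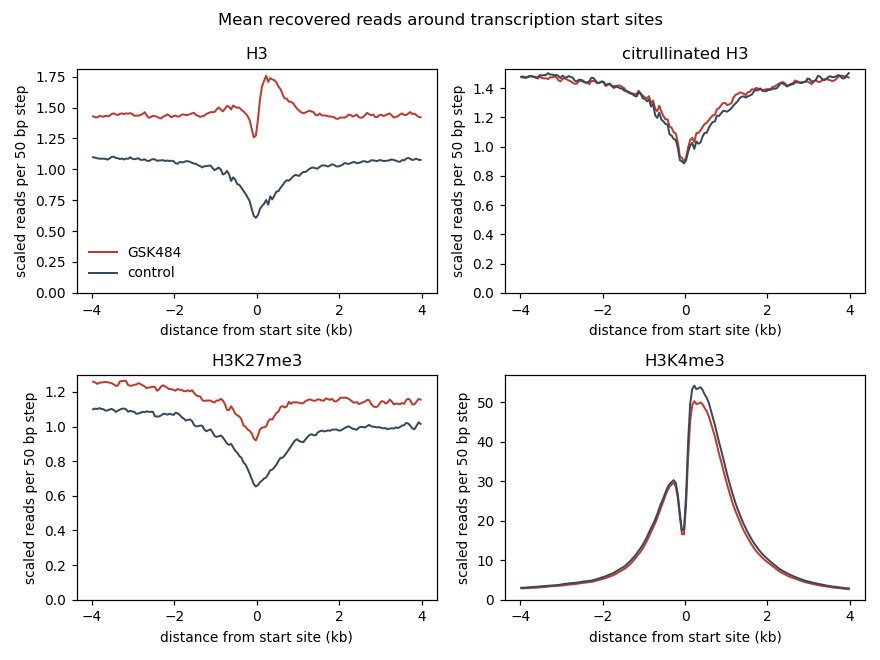
Mean scaled reads per 50 bp (vertical axes, each starting at 0) against distance from the start site in kb, for GSK484 (red) and control (dark) libraries, 1 library each. H3 dips at the start site in both libraries, more deeply in control, and averages 0.84 reads within 1 kb of it in control and 1.54 with GSK484, and the H3K4me3 curves differ little in shape.

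Among the 10 genes with the highest H3 ratio was OPLAH, which encodes 5-oxoprolinase of glutathione metabolism (start site at chromosome 8, 145115584), with 49 against 6 reads, a 7.87-fold ratio (95% interval 4.24 to 28.3). MYBPH, a myosin-binding protein gene on chromosome 1 at 203144942, had 59 against 10 reads (6.20-fold, 3.63 to 15.7). PTPN9, a tyrosine phosphatase gene on chromosome 15, had 45 against 3 reads (12.5-fold, 5.84 to 91.4). The other 7 entries among the 10 highest were DUX4 and copies of it in repeats of chromosomes 4 and 10, with mean log2 ratios of 1.63 to 1.73. Several share a start site or lie a few bp apart, so they hold 3 separate windows, and reads in such repeats cannot be placed with certainty. At the low end, WDR49 had 2 reads against 35 (0.10-fold, 0.008 to 0.27), MNDA, a myeloid nuclear antigen gene, 6 against 41 (0.22-fold, 0.06 to 0.42), and the intestinal disaccharidase gene SI 3 against 31 (0.16-fold, 0.02 to 0.38). CFHR4, encoding a complement factor H-related protein, had 0 GSK484 and 33 control H3 reads. CTAGE5 was low at the chosen start site (-1.07) but not at the first one listed for it (0.25).

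Of the 26 gene lists, 9 stood apart in H3. The lists below all genes were families of neighbouring genes. The 375 olfactory receptor genes had a median of -0.20 (percentile 0.00 of random lists), from OR5H15 at -1.05 to OR2Z1 at 0.96. The 57 clustered protocadherin genes, encoding neuronal adhesion proteins, had a median of -0.11 (percentile 0.00), and the 88 keratin-associated protein genes of hair had 0.03 (percentile 0.00). Within that family, KRTAP6-1 and KRTAP20-2 on one part of chromosome 21 were at -0.80 and -0.77, and KRTAP10-11 on another part of the same chromosome at 1.23. Members of such families are neighbours and do not count as independent genes. Replication-dependent histone genes were also low at 0.21 (73 genes, percentile 0.14), but lay inside the central 95% under 3 of 8 alternatives, among them lists matched on reads (percentile 3.29).

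The lists above all genes in H3 held regulators of development, epithelial genes, and genes of neurons and of neutrophils. The 49 developmental transcription factors had a median of 0.65 (percentile 99.95), with LHX9 at 1.35 (56 against 12 reads, 5.19-fold, 3.0 to 11.6) and the endoderm and heart factor GATA4 at 1.18 (36 against 7). The 16 epithelial junction genes had a median of 0.69 (percentile 99.2). All 16 were above 0 and 11 above the median of all genes. The list lay inside the central 95% with the 0.5 kb window (90.1) and with the first transcript per gene (94.9). Among them were the tight junction gene CLDN7 at 1.21 (43 against 10 reads, 4.74-fold, 2.58 to 11.6) and CDH1, encoding E-cadherin, at 0.97 (30 against 8, 4.27-fold, 2.04 to 11.5). The 39 HOX genes were at 0.58 (percentile 97.65), with HOXB1 at 1.18 and HOXD13 at -0.01; this lay inside the central 95% under 4 of 8 alternatives, among them the 0.5 kb window (85.6) and lists matched on reads (97.2). The 15 neuronal genes were at 0.69 (percentile 98.7), but inside under 4 of 8 alternatives, among them the 8 kb window (72.4) and summed reads (92.5). The 6 genes of neutrophil extracellular traps were at 0.87 (percentile 99.5), led by ELANE, encoding neutrophil elastase, at 1.04. The neutrophil genes lay inside under 4 of 8 alternatives, among them summed reads (87.4) and lists matched on reads (96.9). Of them, AZU1, PRTN3 and ELANE are neighbours on chromosome 19, which had the highest H3 flank ratio (0.86). HOX genes lie in clusters as well, and such neighbours do not count as independent genes.

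Citrullinated H3, the product of PADI4, differed little between the libraries in scaled reads averaged over all promoters. Its reads per 50 bp within 1 kb of start sites were 1.16 with GSK484 and 1.12 in control, with flanks of 1.46 and 1.48. The median promoter had a mean log2 ratio of 0.06 in the authors' deposited table (quartiles -0.10 and 0.22, 23259 genes), and of 0.00 with the median of bins. A single gene, PPP2R5A, reached a mean log2 ratio of 1 and none reached -1, where counting noise alone gave 0.15 and 0 genes on average. On summed reads, for which counting noise was not simulated, 1224 genes were at 2-fold or more and 316 at 0.5-fold or less. In the mean log2 ratio, counting noise accounted for 84.7% of the variance between genes, against 29.8% for H3. Values upstream and downstream of the start site were nearly unrelated across genes (Spearman rho 0.05, against 0.37 for H3). The larger library of each pair was scaled down, so a loss of the mark shared by the whole genome could be hidden. These values therefore do not show that GSK484 left citrullination unchanged.

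PPP2R5A, encoding a regulatory subunit of protein phosphatase PP2A, had 46 citrullinated H3 reads with GSK484 and 12 in control (3.20-fold, 1.71 to 6.79; chromosome 1, 212475148). The paternally expressed zinc finger gene PEG3 was at 0.91 (77 against 29 reads, 2.18-fold, 1.46 to 3.60), but at -0.03 at the first start site listed for it. The lowest were HAUS5, encoding an augmin subunit of the spindle, at -0.88 (13 against 34 reads, 0.34-fold, 0.16 to 0.64), and EBP, a sterol isomerase gene, at -0.88 (14 against 36, 0.35-fold, 0.17 to 0.63). These genes were picked as extremes of a track in which counting noise is most of the variance. Their intervals make no allowance for that and do not establish differences at single genes. Because the H3 ratio was high, citrullinated H3 minus H3 had a median of -0.34 on the log2 scale (quartiles -0.65 and 0.00), below 0 at 74.8% of 23256 genes. The median was -0.80 on summed reads and -0.15 over the 8 kb window.

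Of the 26 lists, 8 stood apart in citrullinated H3, all by less than 0.30. Developmental transcription factors (-0.05, percentile 0.23) and HOX genes (-0.05, percentile 1.21) were below all genes, with the heart factor TBX20 at -0.67 (14 against 31 reads). Ribosomal protein genes were above at 0.16 (82 genes, percentile 99.8), with RPS6 at 0.76 (47 against 17 reads, 2.35-fold, 1.33 to 4.38) and RPL32 at -0.47. Breast stem cell markers were at 0.26 (15 genes, percentile 99.4), with the drug efflux transporter gene ABCG2 at 0.51 (25 against 10 reads) and PROCR at -0.27. The 5 peptidylarginine deiminase genes had a median of 0.35 (percentile 98.9), PADI2 standing at 0.41 and PADI1 at -0.42. The remaining 3 lists were p53 targets (0.19, percentile 98.2), histone genes (0.14, percentile 98.9) and olfactory receptors (0.02, percentile 0.13). All 3 lay inside the central 95% with lists matched on reads, at 96.0, 95.5 and 87.1. Under the median of bins or the 8 kb window, each of the 8 lists lay inside at least once; the p53 targets lay inside under 8 of 9 alternatives and the HOX genes under 5 of 9. Subtracting the H3 difference moved the olfactory receptors to percentile 100.

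**Figure D2:**
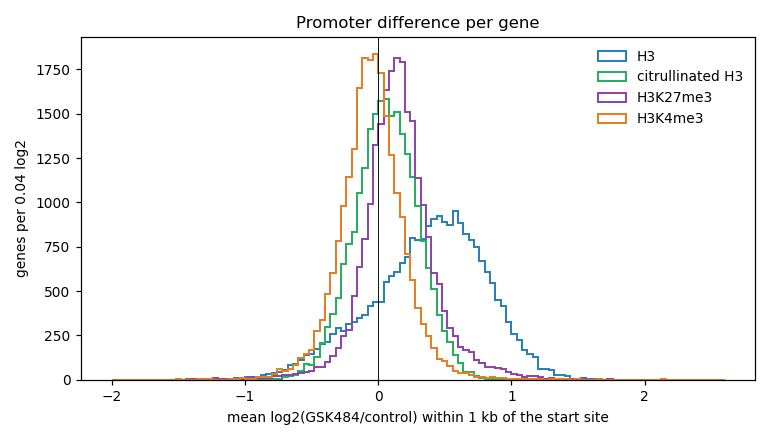
Number of genes (vertical axis, per 0.04 log2) against the mean log2 ratio of GSK484 over control within 1 kb of the start site, 1 line per antibody. H3 is centred at 0.42 and is the widest, and the other antibodies lie near 0.

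H3K27me3, the mark of Polycomb repression, was higher in the GSK484 library, with a median of 0.14 in the authors' deposited table (quartiles 0.00 and 0.29, 23250 genes) and of 0.51 on summed reads. The median was 0.00 with the median of bins and turned to -0.25 when the H3 difference was subtracted. The log2 ratio of total reads was 0.91 in the 20% of promoters with the fewest H3K27me3 reads, at medians of 3.63 and 1.61 reads. It was 0.29 in the 20% with the most. The median of the mean log2 ratios went the other way, from 0.10 to 0.26, but that measure understates differences where reads are few. Promoters were ranked by the same reads that were compared, and citrullinated H3 ranked by its own reads also fell, from 0.30 to -0.06. No test of sorting or of background reads was made for H3K27me3, so these values do not show where the mark itself rose. The mean log2 ratio was 1 or more at 173 genes and -1 or less at 65, where counting noise alone gave 2.30 and 0. On summed reads 6395 genes were at 2-fold or more and 718 at 0.5-fold or less, many on few reads. Centring changed the split by mean log2 ratio to 83 and 104. Genes with more H3K27me3 reads under GSK484 included FXYD6, which encodes a regulator of the sodium pump (chromosome 11, 117747746; 91 against 16 reads, 5.25-fold, 3.18 to 9.93). WNT6, encoding a Wnt ligand (chromosome 2, 219724546), had 104 against 19 reads (5.02-fold, 3.19 to 9.06). CXCL14, a chemokine gene of epithelia (chromosome 5, 134914969), had 77 against 16 (4.36-fold, 2.67 to 8.46), and the calcium exchanger gene SLC24A4 had 111 against 29 (3.63-fold, 2.42 to 5.72). The potassium channel gene KCNA2 was at 1.65 (127 against 28 reads) but at 0.06 at the first start site listed for it, and the laminin receptor gene ITGA7 at 1.53 and 0.78.

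Lower H3K27me3 was found at 3 neighbouring interferon alpha genes on chromosome 9: IFNA4 (start site 21187598) had 13 against 75 reads (0.18-fold, 0.08 to 0.30), IFNA14 had 19 against 89 and IFNA16 27 against 100. SATB1, encoding a chromatin organiser, had 7 against 60 reads at one start site (0.13-fold, 0.04 to 0.25; chromosome 3, 18480265), with a mean log2 ratio of -1.75 there and -0.47 at the first one listed. GAS2 had 15 against 79 (0.20-fold, 0.10 to 0.32), A1CF, an RNA editing cofactor gene, 36 against 133 (0.27-fold, 0.17 to 0.38), and the fatty acid-binding protein gene FABP4 13 against 58 (0.23-fold, 0.11 to 0.40).

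Of the 26 lists, 4 stood apart in H3K27me3. The p53 target genes were at 0.28 (20 genes, percentile 99.3), but on few reads per gene (the highest, PHLDA3, had 12 reads against 1), and lay inside under 4 of 8 alternatives, among them the 0.5 kb window (53.8) and the 8 kb window (59.1). Keratin-associated protein genes were at 0.24 (percentile 99.9), led by KRTAP10-9 at 1.12 (40 against 6 reads, 5.21-fold, 2.69 to 18.4), and blood cell genes at 0.30 (percentile 99.3), led by the globin gene HBA1 at 0.89. Both lay inside the central 95% against lists matched on reads (73.7 and 86.1), on summed reads (7.45 and 81.3) and over 8 kb (84.7 and 81.2). Olfactory receptor genes were below all genes at 0.08 (percentile 0.00), yet ran from OR5K4 at -1.49 to OR7D4 at 1.53 (64 against 10 reads, 5.40-fold, 3.13 to 13.4). Their call ended with the median of bins (50.0) and turned to percentile 100 when the H3 difference was subtracted.

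H3K4me3, which marks active promoters, was almost level between the libraries as a whole, while single genes differed widely and on many reads. The median was -0.05 in the authors' deposited table (quartiles -0.19 and 0.09, 23253 genes), and 0.00 with the median of bins and -0.47 when the H3 difference was subtracted. Without subtraction, the mean log2 ratio was 1 or more at 48 genes and -1 or less at 26, where counting noise alone gave 0.05 of each. On summed reads 877 genes were at 2-fold or more and 600 at 0.5-fold or less. The gene with the highest ratio was LSAMP, encoding a neuronal adhesion protein (chromosome 3, 116164385), with 248 reads against 17 (14.4-fold, 9.29 to 26.5). PADI1, a relative of PADI4 expressed in epidermis (chromosome 1, 17531621), had 173 against 21 (8.40-fold, 5.43 to 14.2). Precursors of the cornified envelope of squamous epithelia were also among the 10 highest: SPRR1A (chromosome 1, 152956564; 106 against 10, 9.63-fold, 5.77 to 23.7) and SCEL (chromosome 13, 78109809; 306 against 71, 4.43-fold, 3.45 to 5.89). TCN1, encoding a vitamin B12 carrier of secretions, had 472 against 72 reads (6.75-fold, 5.31 to 8.87), ARL14 304 against 65 (4.82-fold, 3.71 to 6.46), and the ubiquitin ligase gene TRIM31 127 against 21 (5.96-fold, 3.95 to 10.5).

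The genes with the lowest H3K4me3 ratios had varied functions. TNIP1, encoding an inhibitor of NF-kappa-B signalling, had 171 against 761 reads at the start site on chromosome 5 at 150466747 (0.24-fold, 0.20 to 0.28), with a mean log2 ratio of -1.74 there and -0.06 at the first one listed, at 150460645. MYLK, encoding myosin light chain kinase, had 99 against 375 reads (0.28-fold, 0.22 to 0.34), the bradykinin receptor gene BDKRB1 34 against 125 (0.29-fold, 0.19 to 0.42), and the carboxypeptidase gene CPA4 90 against 338 (0.28-fold, 0.22 to 0.35). LOXL4, encoding a collagen cross-linking enzyme, had 95 against 279 (0.36-fold, 0.28 to 0.45). The cytokine genes LTB and IL32 had 91 against 259 (0.37-fold, 0.29 to 0.47) and 16 against 67 (0.26-fold, 0.13 to 0.43). CELSR1, a planar cell polarity gene, had a mean log2 ratio of -1.25 but 310 against 457 summed reads (0.71-fold, 0.61 to 0.82).

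Of the 26 lists, 9 stood apart in H3K4me3. Mesenchymal transition genes were lower (18 genes, median -0.27, percentile 0.01), 7 of them above 0. FOXC2 was at -1.11 (80 against 202 reads, 0.42-fold, 0.31 to 0.54), ZEB1 at -0.63 (117 against 150, 0.81-fold, 0.63 to 1.04) and MMP2 at 0.41 (329 against 321, 1.07-fold, 0.91 to 1.25). Wnt, Notch and Hedgehog genes were lower (25 genes, -0.21, percentile 0.11), with the Notch ligand gene DLL1 at -0.50 (737 against 1038 reads, 0.74-fold, 0.67 to 0.81). Both lists lay inside the central 95% on summed reads, over the 8 kb window and after subtraction of the H3 difference, and the mesenchymal genes also with the 0.5 kb window (5.62). Histone methylation enzymes were lower (21 genes, -0.18, percentile 0.86) but inside under 7 of 9 alternatives, among them summed reads (30.8), the 0.5 kb window (20.9) and lists matched on reads (3.78). EZH2, the H3K27 methyltransferase, was at -0.44 (872 against 1111 reads, 0.82-fold, 0.75 to 0.89).

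The other 6 lists were higher in H3K4me3. Clustered protocadherin genes were at 0.19 (57 genes, percentile 100), 41 of them above 0, with PCDHB7 at 0.84 (38 against 15 reads, 2.56-fold, 1.42 to 5.16) and PCDHB13 at 0.75 (85 against 43, 2.04-fold, 1.41 to 3.04). Replication-dependent histone genes were at 0.12 (73 genes, percentile 100), 53 above 0, with HIST1H1B at 0.49 (242 against 154 reads, 1.63-fold, 1.33 to 2.01) and HIST1H3E at -0.26. Zinc finger genes with ZNF symbols, many of them KRAB repressors, were at 0.03 (485 genes, percentile 100), from ZNF746 at -0.96 to ZNF559 at 1.33 (137 against 43 reads, 3.28-fold, 2.34 to 4.78). Keratin-associated protein genes (0.09, percentile 100), olfactory receptors (0.05, percentile 100) and blood cell genes (0.12, percentile 99.8) carried few H3K4me3 reads per promoter; the blood genes lay inside under 4 of 9 alternatives, among them lists matched on reads (93.1). With the median of bins the zinc finger, keratin-associated protein and olfactory receptor genes lay inside as well.

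**Figure D3:**
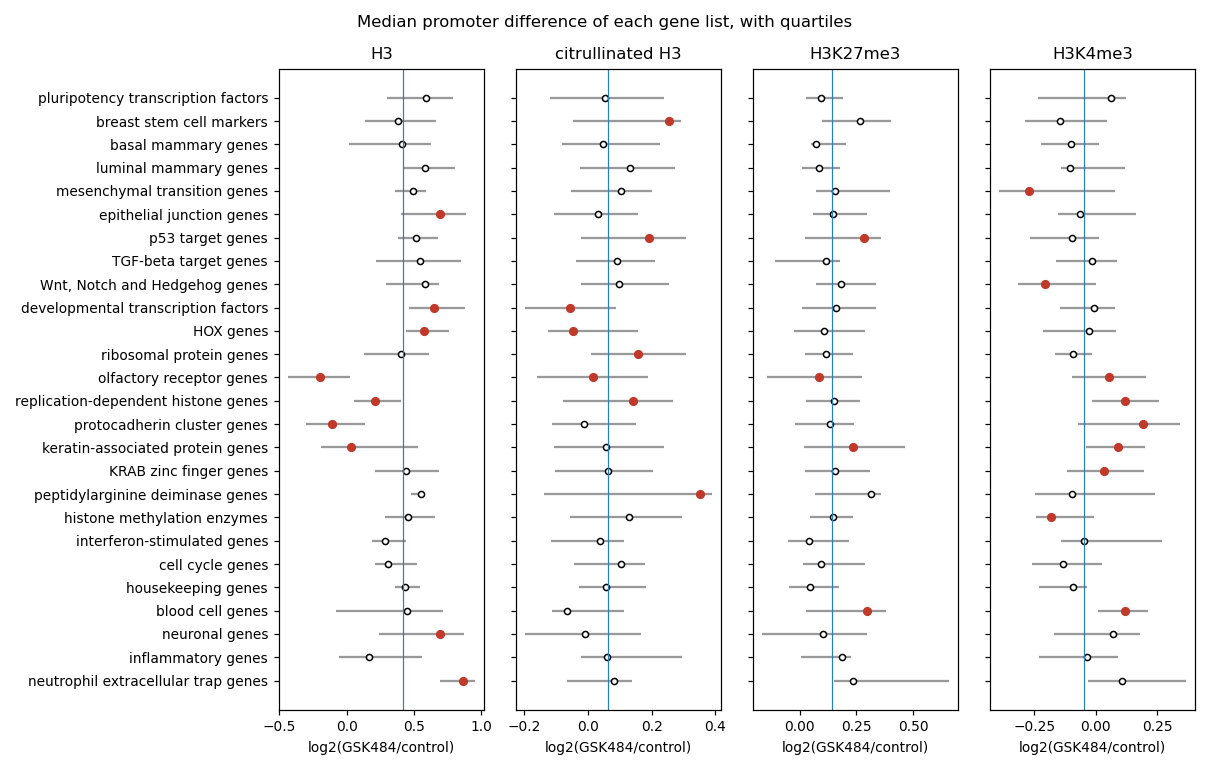
Median log2 ratio of GSK484 over control for each of 26 gene lists (points) with quartiles (lines), 1 panel per antibody. Filled red points are lists outside the central 95% of random lists, and the vertical line is the median of all genes (0.42 for H3). Olfactory receptor genes stand lowest in H3 at -0.20 and mesenchymal transition genes lowest in H3K4me3 at -0.27.

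Genes of stem cells and of the breast, named in advance because the study concerns breast cancer stem cells, showed modest values. MYC had less H3K4me3 with GSK484 (2848 against 3641 reads, 0.81-fold, 0.78 to 0.85), as did the stem cell surface marker CD44 (1115 against 1279, 0.91-fold, 0.84 to 0.98, which spans the -0.10 log2 shared by the most strongly marked promoters). The basal keratin gene KRT5 had fewer summed reads (803 against 1028, 0.81-fold, 0.74 to 0.89) but a mean log2 ratio of -0.015, above the median of all genes. KLF4 had more reads (1122 against 946, 1.23-fold, 1.13 to 1.35; mean log2 ratio 0.077), and so did the oestrogen receptor gene ESR1 (219 against 169, 1.35-fold, 1.1 to 1.66). CDKN1A, the p53-regulated cell cycle inhibitor, had 363 against 350 (1.08-fold, 0.93 to 1.25). NANOG carried little H3K4me3 (10 against 26 reads, 0.45-fold, 0.17 to 0.86) and more H3K27me3 with GSK484 (39 against 16, 2.30-fold, 1.28 to 4.48, which spans the median promoter's 0.51 log2). SOX2 had 39 against 16 reads of H3 (2.84-fold, 1.61 to 5.66), an interval that spans the median promoter's 0.93 log2, and POU5F1 had 12 against 9 reads of H3K4me3 (1.42-fold, 0.54 to 3.73). PADI4 itself, on chromosome 1 at 17634690, had 27 against 15 reads of citrullinated H3 (1.53-fold, 0.79 to 3.11) and 12 against 17 of H3K4me3 (0.80-fold, 0.32 to 1.63), both intervals spanning equality, beside 29 against 17 of H3 (2.00-fold, 1.1 to 4.01), no different from the median promoter within counting error. As lists, the 14 pluripotency factors lay inside the central 95% for H3, citrullinated H3, H3K27me3 and H3K4me3 (percentiles 91.4, 45.6, 22.4 and 95.6), and so did basal and luminal mammary, TGF-beta target, interferon-stimulated, cell cycle, housekeeping and inflammatory genes for each of these antibodies.

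Across genes, which are not independent replicates, the differences of the antibodies were related to degrees that varied with the processing. The H3 and H3K27me3 differences had a Spearman rho of 0.23 over 23249 genes, and of 0.42 over the 8 kb window and 0.44 with the filter on bins at 0 (6037 genes). H3 and H3K4me3 had -0.12 (-0.19 over 8 kb), and citrullinated H3 and H3K4me3 -0.07. The other 7 of the 10 pairs, RNA included, lay between -0.04 and 0.02, but over 8 kb H3 and citrullinated H3 had -0.155 and citrullinated H3 and H3K27me3 -0.12, and with the filter H3K27me3 and H3K4me3 had -0.16. Promoters were grouped by whether the control library placed them above the upper quartile of H3K4me3 or H3K27me3 reads. The 5700 with H3K4me3 alone had a median citrullinated H3 difference of 0.14 and an H3 difference of 0.47, and the 5613 with H3K27me3 alone had 0.01 and 0.18. On summed reads the citrullinated H3 medians of these groups were 0.29 and -0.03. Over 8 kb their H3 differences were 0.17 and 0.01. The 136 with both had a median H3K27me3 difference of -0.003. When both libraries together set the groups, 90 promoters had both marks and the value was 0.15.

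The RNA-seq track in the authors' deposited table gave 52 genes at a mean log2 ratio of 1 or more and 27 at -1 or less of 17197, led by the zinc transporter gene SLC39A4 at 1.72. The 747 genes with a mean RNA log2 ratio at or above the log2 of 1.5 had a median H3 difference of 0.50, at percentile 100 of random lists, and a median H3K4me3 difference of -0.08, at percentile 0.00. The H3K4me3 value lay inside the central 95% over 8 kb (4.69), with the median of bins (50.0) and after centring (3.65). The 339 at or below minus the log2 of 1.5 had H3 at 0.44 (percentile 78.4) and H3K4me3 at -0.05 (percentile 44). Their citrullinated H3 was at 0.095 (percentile 97.9), just outside the central 95%. The random lists for these RNA groups were not matched on reads. Promoters with H3K4me3 alone in control already had medians of 0.47 in H3, 0.14 in citrullinated H3 and -0.11 in H3K4me3. Whether genes with an RNA value were mostly such promoters was not examined. The percentiles therefore cannot tell a relation to RNA change from values shared by marked promoters. Replication-dependent histone genes had a median RNA ratio of -0.20 (66 genes, percentile 0.00) beside their higher H3K4me3. The RNA ratios were averaged within 1 kb of start sites, not over whole transcripts, and the track's libraries are not described in the labels used here.

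**Figure D4:**
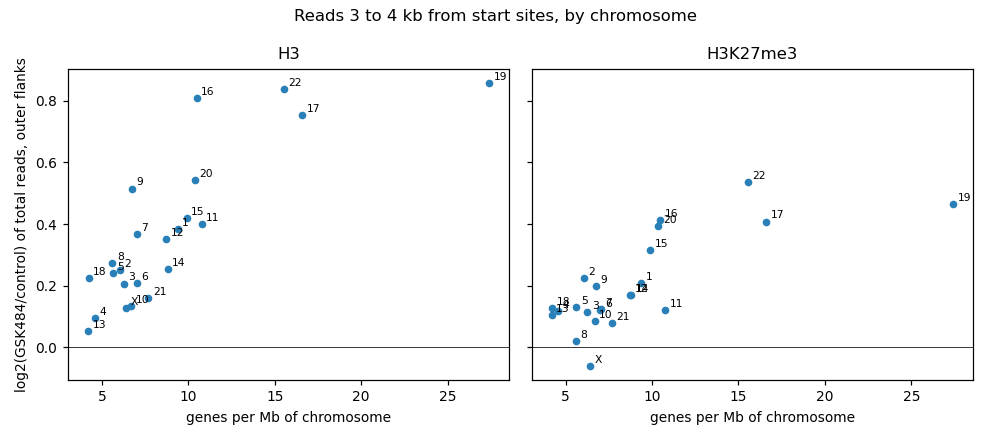
Log2 ratio of total GSK484 over control reads in the flanks 3 to 4 kb from start sites (vertical axis) against genes per Mb (horizontal axis), 1 numbered point per chromosome, for H3 and H3K27me3. H3 runs from 0.05 on chromosome 13 to 0.86 on chromosome 19.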

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

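The recovered-read settings were chosen after seeing the data. Pseudocounts other than 1 read and IgG subtraction were not run, because the deposited tracks are ratios, and no region groups of the authors were used. No paired analysis was possible because each group had 1 library. Medians and counts below are in the order H3, citrullinated H3, H3K27me3 and H3K4me3 unless named, with counts as genes at 1 or more and at -1 or less. The causes of the differences were not tested except where the setting itself makes them. With 0.5 kb either side, the medians were 0.50, 0.067, 0.15 and -0.042. The counts were 2805 and 95 for H3, 29 and 15 for citrullinated H3, 345 higher for H3K27me3, and 78 and 170 for H3K4me3. Over the whole 8 kb window the medians were 0.18, 0.039, 0.12 and -0.042, with counts of 146 and 0 for H3, 0 higher for citrullinated H3, 26 higher for H3K27me3, and 9 and 5 for H3K4me3. With the median of bins, the medians were 0.18 for H3 and 0.00 for the other 3. The counts were 4095 higher for H3, 2 and 17 for citrullinated H3, 127 lower for H3K27me3, and 130 and 17 for H3K4me3. With the filter on bins at 0 the medians were 0.44, 0.052, 0.23 and -0.076. Centring, which moves every gene by the median, gave 46 and 482 genes for H3, 0 higher for citrullinated H3, 83 and 104 for H3K27me3, and 15 lower for H3K4me3. With the threshold on the mean ratio lowered to the log2 of 1.5, the counts were 7819 and 468, 281 and 93, 1274 and 257, and 252 and 414.

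Subtracting the H3 difference, which is high at most promoters, reversed the medians of citrullinated H3 (-0.34) and H3K27me3 (-0.25) and moved that of H3K4me3 to -0.47. The counts became 160 and 1646 for citrullinated H3, 581 lower for H3K27me3, and 158 and 2683 for H3K4me3. It also reversed olfactory receptor genes, low in H3, to percentile 100 in citrullinated H3 and in H3K27me3. It turned the class medians negative: -0.20 in citrullinated H3 for promoters with both marks, -0.33 in citrullinated H3 and -0.33 in H3K27me3 for those with H3K4me3 alone, -0.041 in H3K27me3 and -0.14 in H3K4me3 for those with H3K27me3 alone, and -0.41 in citrullinated H3 and -0.29 in H3K27me3 for those with neither. On summed reads, which are not pulled to 0 by the pseudocount in every bin, the medians were 0.93, 0.078, 0.51 and -0.062, with counts of 10879 and 814, 1224 and 316, 6395 and 718, and 877 and 600. Citrullinated H3 minus H3 stayed below 0 throughout, at -0.41 (0.5 kb), -0.15 (8 kb), -0.24 (median of bins) and -0.80 (summed reads).

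The number of lists outside the central 95% was 9 for H3 and 9 for H3K4me3 and stayed within 1.5 times under each alternative run. For citrullinated H3 it went from 8 to 4 (0.5 kb), 5 (8 kb), 4 (median of bins), 5 (filter on bins at 0), 5 (summed reads) and 5 (lists matched on reads). For H3K27me3 it went from 4 to 1 (median of bins), 2 (filter on bins at 0) and 8 (H3 subtracted). Of 1070 list percentiles under alternatives, 919 kept their side of the central 95%, among them those of lists never set apart. Of the rest, 86 lost their call, 2 turned to the opposite side and 63 moved outside. Of 1793 values for genes within the naming rule, 1656 moved by no more than 0.5 of the width of their counting interval. Among the genes with a mean of 1 or more in size only CTAGE5 changed sign, in H3 (0.25 at the first start site listed). Smaller means changed sign too, among them PEG3 in citrullinated H3 (-0.025 at the first start site listed). Rank correlations also moved in size, that of H3 and H3K27me3 from 0.23 to 0.42 (8 kb) and 0.44 (filter on bins at 0) and that of H3 and citrullinated H3 to -0.155 (8 kb). Small ones changed sign: H3 and citrullinated H3 to 0.012 (0.5 kb) and 0.049 (summed reads), and citrullinated H3 and H3K27me3 to 0.025 (summed reads). The class with both marks was at -0.054 in H3 over 8 kb. The start site against flank difference kept its direction with a flank of 0.5 kb for each antibody. The H3K4me3 percentile of genes with higher RNA left the lowest 2.5% over 8 kb (4.69), with the median of bins (50.0) and after centring (3.65), which also shifts the RNA ratio and so regroups the genes. Depth limited single genes to a degree that differed by antibody: counting alone explained 84.7% of the variance between genes in citrullinated H3, 49.9% in H3K27me3, 43.0% in H3K4me3 and 29.8% in H3.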

Other observations

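The H3 and H3K27me3 differences also followed chromosomes. In the flanks, 3 to 4 kb from start sites, the ratio of GSK484 to control H3 reads was highest on gene-dense chromosomes 19 (0.86 on the log2 scale), 22 and 16 and lowest on gene-poor chromosomes 13 (0.05) and 4. The same flanks of H3K27me3 ran from -0.06 on chromosome X to 0.54 on chromosome 22, with a Spearman rho of 0.69 against genes per Mb over 23 chromosomes. Citrullinated H3 went the opposite way in a narrower range (rho -0.67), from -0.07 on gene-dense chromosome 19 to 0.05 on chromosome 13. Chromosome 10, which is not gene-dense (6.68 genes per Mb), stood apart from that trend at -0.13. It also had the lowest H3K4me3 ratio at start sites (-0.26, the next lowest being -0.14 on chromosome 22) and the lowest of citrullinated H3 there (-0.085). Its flanks were toward the low end in H3 (0.135) and H3K27me3 (0.085) too, though chromosomes 13 and X respectively were lowest. The lower ratios of chromosome 10 were thus not confined to 1 mark, and their cause was not tested. ZEB1, which lies on chromosome 10, had -0.30 in H3K4me3 on summed reads.

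The tests of H3K4me3 carry-over and of depth scaling were chosen after the result was seen, and the chromosome test was set before its values were computed. Reads from H3K4me3-marked chromatin mixed into the GSK484 library do not alone account for its higher H3 at promoters. The 20% of promoters with the least H3K4me3 had 65.5% of the extra H3 reads of the highest 20%, and no H3K4me3 above its flank. A partial contribution stays open, because the highest 20% had the most extra H3 (0.49 reads per 50 bp, against 0.20 to 0.35 in the other groups). A wrong depth scaling is argued against for the rise at the start site relative to the flank. The start site over flank ratio, which no scaling alters, was 1.37 times higher with GSK484. That ratio cannot address the higher flank itself (1.44 against 1.08 scaled reads per 50 bp), so scaling stays open for that part. A base composition bias between the 2 libraries stays open as a hypothesis: gene density, which stands in for GC content because no genome sequence was used here, tracked the flank ratio with a rho of 0.81 over 23 chromosomes, and such a bias may also underlie the H3 order of the gene lists. A true gain of H3 in gene-rich chromatin after PADI4 inhibition would give the same trend, was not tested, and needs replicate libraries or an input.

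The test of background reads was chosen after its values had been seen, and the test of sorting before. H3K4me3 reads with GSK484 were lower at strongly marked promoters (-0.10 on the log2 scale in the highest 20%) and higher at weakly marked ones (0.080 in the lowest 20%). A larger share of background reads may account for part of it and stays open: the 20% of promoters with the least H3K4me3 had 6.01% more reads with GSK484 in the flank (4.10 to 7.95 over resampled genes) and 5.68% more at the start site, but the middle 20% lay 0.054 above what a uniform background predicts. Sorting promoters on the reads compared is argued against: sorted on one side of the start site and compared on the other, the highest group still differed from the lowest by -0.125 and -0.192, although sorting on H3K27me3 and on citrullinated H3 reads gave ranges of 0.135 and 0.085, on either side of the limit of 0.1 set beforehand. Variation between immunoprecipitations may produce a trend of this size, which 1 library per group leaves open, and the label doubt applies to its direction.

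The test by numbers of genes was chosen after the values were seen, and the test by medians before. SPRR1A, SCEL and PADI1 among the highest H3K4me3 ratios raised the hypothesis that genes of the cornified epithelium gain this mark with GSK484. Further genes of that programme were listed before their values were examined. In the epidermal differentiation cluster and elsewhere they did not leave what chance gives among genes of like reads. The 34 cluster genes had a median of 0.08 (percentile 87.5), with 18 above 0 and totals of 707 against 595 reads. In reads, 5 genes were at 2-fold or more (percentile 95.6), led by FLG (30 against 7) and SPRR1B (39 against 10), a close relative of SPRR1A. The 30 genes elsewhere had a median of -0.02 (percentile 55.9), with 14 above 0 and totals of 7724 against 8003 reads (0.006 on the log2 scale after scaling). There 3 genes were at 2-fold or more (percentile 88.6), among them ABCA12 (189 against 82). Others were lower, among them GRHL1 (792 against 1183) and KRT1 (2 against 10). A shared gain of the mark stays open and no biological explanation was tested.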
